A study of Homo sapiens
Mus musculus with 17 samples.

How the data were processed

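RNA of 17 xenograft tumours was measured, each as 1 sequencing library. The tumours were grown from VM-CUB-1, a human bladder cancer cell line, in athymic nude mice. Per the labels' protocols, polyA RNA was made into libraries with the TruSeq RNA v2 kit and sequenced as 75-bp paired-end reads on a NextSeq500, and mice were treated for 7 days before the tumours were taken. Per the submitters' processing notes, reads were mapped with Bowtie and TopHat and normalized with DESeq2 against the builds hg19 and mm10, with no versions given. The series description adds that the reads were mapped separately to the human and the mouse genome. The read counter, the gene annotation and the strand setting were not given in the sources used here.

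The deposited data are 2 tables, of 23368 human and 23337 mouse gene symbols by 17 libraries. Their values are normalized counts, a per-gene signal that the authors obtained by dividing read counts by a size factor per library. Every library was recovered as whole reads: after each column was divided by its smallest step, all values (100%) lay within 0.001 of a whole number, with a largest distance of 8.97e-05 in the human and 0.000384 in the mouse table. DESeq2 median-ratio factors computed from the recovered reads equalled the deposited scaling, with a largest difference of 1.94e-08% for human and 9.79e-09% for mouse. The deposited values were used without further scaling. Neither table holds mitochondrially encoded genes. The human list of carry-over from host cells and the mouse list of carry-over from tumour and skin were included because reads of conserved genes can map to both genomes. For genes named alike in both tables, mouse and human reads were compared over the 17 libraries.

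Groups were taken from the sample titles: 4 vehicle, 4 alpelisib, 4 combination, and 5 nintedanib libraries, of which the titles call 3 responders and 2 non-responders. The series description gives 2 responders and 3 non-responders, so the titles were followed and the conflict stays open. Replicate numbers were not treated as pairs: same-number libraries of different groups correlated above 0.1 in 3 of 12 cases (human) and 2 of 12 (mouse), against 14 of 36 for different numbers in each table. No library was a copy of another within its group (chi-square per gene at least 18.61 in human and 14.4 in mouse reads over 22 pairs each).

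The following choices were made before the data were examined: the samples and groups, the contrasts, the test, the gene lists, the rule for named genes and most alternative settings. Genes with a mean of at least 10 normalized counts over the 17 libraries were tested, 14533 human and 11831 mouse. The values plus 1 were log2-transformed and fitted with limma-trend, with 1 mean for each of the 5 groups. Per species 7 contrasts were tested: each treatment against vehicle, the combination against each drug alone, responders against non-responders, and the departure from additivity, which is combination plus vehicle minus alpelisib minus nintedanib. The nintedanib mean weighted its 5 libraries equally. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a species. Changes are log2 fold changes with their standard error (SE) from limma, and levels are mean normalized counts with their standard deviation (SD).

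Gene lists, 21 human and 23 mouse, were tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of 1 species within a contrast, and repeated with an estimated correlation and with fry. Of these, 20 lists per species had at least 5 members past the expression filter and were tested. Not tested were the mitochondrially encoded lists of both species, with 0 genes in the tables, and the mouse B and plasma cell and erythroid lists, with 3 and 1 members past the filter. Genes carry the symbols of the tables, so that IL8, CYR61, CTGF, PKM2, SC5DL and mouse Emr1 stand for members listed under newer names. The mouse share of reads was compared with exact two-sided permutation tests (70 orders for 4 against 4 libraries and 126 for 5 against 4), adjusted over the 3 treatments.

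Genes were named by rule: up to 6 with the largest increase and 6 with the largest decrease among those past the threshold with a mean of at least 50 normalized counts in a compared group, leaving out unnamed gene models, pseudogenes, and immunoglobulin and T cell receptor genes; up to 4 members with the smallest p of each list; and the drug targets PIK3CA, PIK3CB, PIK3CD, FGFR1, FGFR2 and FGFR3 in human, and Pik3ca, Kdr, Flt1, Flt4, Pdgfra, Pdgfrb and Fgfr1 in mouse. The filter on gene names was rewritten after first results were seen, to follow the written rule; among passing genes this concerned C10orf10 and LINC00162, neither of them among the top genes.

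Alternatives tried were TMM scaling, pseudocounts of 0.5 and 5, no expression filter and a minimum of 50, edgeR, limma-voom and DESeq2 on the recovered reads, a block for the replicate number, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were sample quality weights, a covariate for ribosomal RNA, a fit without 4 libraries in which over 40% of mouse reads came from Rn45s and Lars2, a fit of only genes with more mouse than human reads, lists without Vehicle replicate 3 and without each library of the compared groups in turn, and DESeq2 with other filtering settings. A test of dilution that pooled fibroblast, macrophage and pericyte genes was replaced by one on pericyte genes, because the first 2 cell types would be the diluting ones. Scaling alternatives moved the median of all genes by less than 0.1 on the log2 scale.

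The calls were tested on simulated data with the same group sizes, depth and spread between libraries. At 4-fold changes, limma recovered 92.5% of changed human genes for alpelisib and for nintedanib against vehicle and 94% for the combination, and 86.6%, 86.6% and 74.6% of changed mouse genes. At 2-fold changes these shares were 40.3%, 47.8% and 37.3% in human and 19.4%, 29.9% and 13.4% in mouse. For responders against non-responders, 82.1% of human and 68.7% of mouse genes with 4-fold changes were recovered, and 7.46% and 10.4% at 2-fold. Of 162 human and 128 mouse calls in the combination contrast, 8 were false in each species. The simulation held no correlation between genes. Shares of single libraries carry 95% Wilson intervals, which cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Depth per library is given with the results. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9. No coordinates are given, since the tables hold gene symbols only.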

Results

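The data are bulk RNA sequencing of 17 tumours grown from VM-CUB-1, a human bladder cancer cell line, in athymic nude mice. Mice received vehicle (0.5% methylcellulose with 0.1% Tween80, n = 4), alpelisib at 25 mg/kg (n = 4), nintedanib at 40 mg/kg (n = 5) or both drugs (n = 4) for 7 days. Alpelisib (BYL719) inhibits the alpha isoform of phosphoinositide 3-kinase (PI3K). Nintedanib inhibits the receptors of VEGF, FGF and PDGF. The series description calls the xenografts resistant to nintedanib and asks how the 2 drugs act together in vivo. Of the 5 nintedanib tumours, the sample titles call 3 responders and 2 non-responders. Human reads largely represent tumour cells and mouse reads largely represent host cells. The labels do not say whether the tumours of a group came from separate mice, so p-values measure the spread between these samples. Below, changes are log2 fold changes ± SE from limma, and levels are mean normalized counts ± SD.

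Recovered human reads ranged from 7429753 to 25654879 per library (median 20312801), and mouse reads from 2271764 to 7438823 (median 5084126). Libraries differed in the share of mouse reads assigned to Rn45s, the ribosomal RNA precursor, and Lars2, a transcript known to collect ribosomal RNA reads. This share was 72.92% in Vehicle 3 (95% Wilson interval 72.88 to 72.96), 60.06% in Combination 4 (60.02 to 60.09), 44.1% in Alpelisib 3 (44.06 to 44.14) and 42.11% in Combination 1 (42.07 to 42.15). The lowest share was 1.726% in nintedanib responder 2 (1.715 to 1.737). Intervals cover counting error only. Vehicle 3 also had the fewest human reads.

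**Figure D1:**
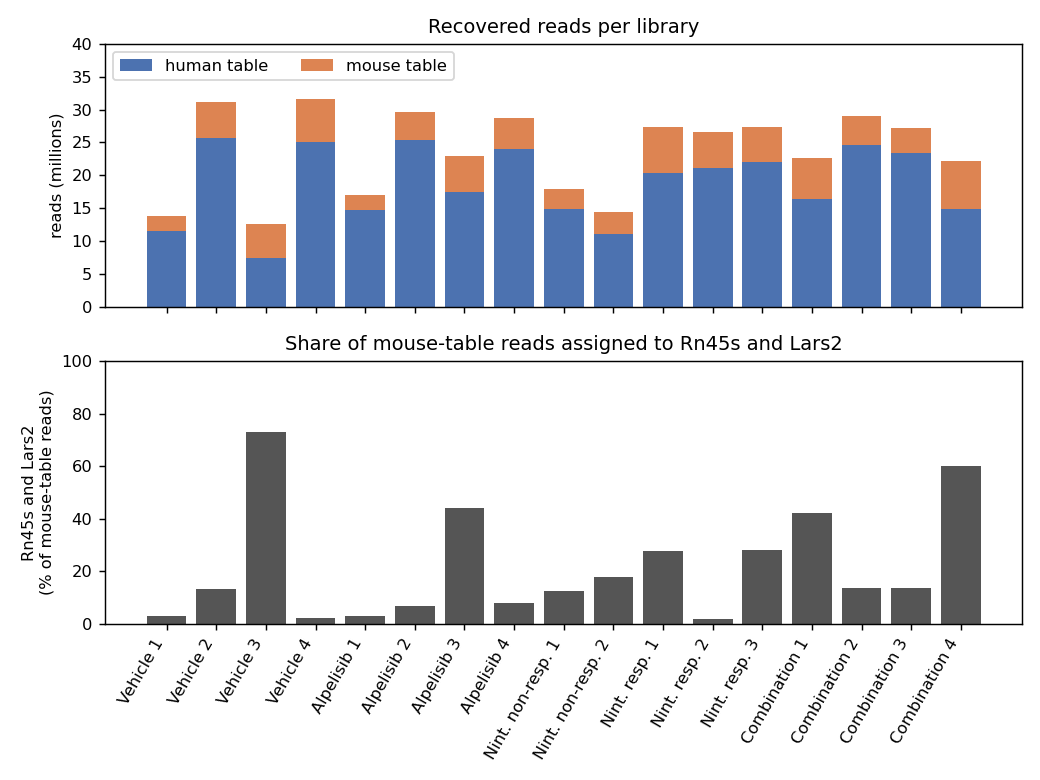
Recovered human and mouse reads of each of the 17 libraries (stacked bars), and the percent of mouse reads assigned to Rn45s and Lars2. Vehicle 3 stands highest in the second panel at 72.92%.

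The mouse share of all reads asks how much of the RNA came from the host, but it also moved with ribosomal RNA: without Rn45s and Lars2, Vehicle 3 went from 40.63% to 15.63% and Combination 4 from 33.45% to 16.72%. Single libraries ranged from 13.42% in Alpelisib 1 (95% Wilson interval 13.4 to 13.43) to 40.63% in Vehicle 3 (40.6 to 40.66). The mean was 23.9% ± 11.3 (SD, n = 4) in vehicle tumours, 16.98% ± 4.71 with alpelisib (n = 4, exact permutation p = 0.286). It was 21.35% ± 3.29 with nintedanib (n = 5, exact p = 0.833) and 22.51% ± 9.41 with the combination (n = 4, exact p = 0.83). The adjusted p was 0.833 for each. With these 2 genes left out, a measure added after the data were seen, the share was 16.98% ± 2.25 in vehicle and 14.18% ± 1.03 in alpelisib tumours. All 4 alpelisib tumours then lay below all 4 vehicle tumours (exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.0858). On this measure nintedanib tumours had 18.18% ± 2.75 (n = 5, exact p = 0.516) and combination tumours 15.09% ± 2.6 (n = 4, exact p = 0.343).

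Alpelisib against vehicle asks what PI3K-alpha inhibition alone did to tumour cells. The human squamous differentiation list, genes of the cornifying cell layers, rose as a group: all 22 measured members were positive with a median change of 1.54 (camera adjusted p = 1.32e-11, and adjusted p = 0.644 with an estimated correlation). No single gene passed over all genes, and 17 squamous genes were higher adjusted over the list alone. KRTDAP, a keratinocyte differentiation-associated gene, had a change of 2.23 ± 0.54 (adjusted p = 0.209), from 1748 ± 1080 to 7545 ± 1990 normalized counts, and SPRR1A, a cornified envelope precursor, 2.04 ± 0.50. Basal urothelial genes rose with a median of 0.63 (14 of 17 positive, 2 higher adjusted over the list alone, adjusted p = 0.000868, and adjusted p = 0.86 with an estimated correlation). Among them were the keratins KRT16 (1.70 ± 0.46, adjusted p = 0.209) and KRT6B (1.84 ± 0.57, adjusted p = 0.21). Angiogenic ligands rose with a median of 0.56 (13 of 16 positive, 5 higher adjusted over the list alone, adjusted p = 0.00532, and adjusted p = 0.644 with an estimated correlation). FGFBP1, an FGF-binding protein, had a change of 1.38 ± 0.37 and PGF, a VEGF family ligand, 1.40 ± 0.47. Glycolysis genes rose with a median of 0.34, with 20 of 20 positive (adjusted p = 0.00398). So did MHC class I (0.43, 11 of 12 positive, adjusted p = 0.0399) and interferon response genes (0.19, 18 of 28 positive, adjusted p = 0.0435, and adjusted p = 0.86 with an estimated correlation for all 3), with 0 genes adjusted over each of the last 2 lists alone.

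Ribosomal protein genes rose with a median of 1.08 after alpelisib (25 of 25 positive, 25 higher adjusted over the list alone, adjusted p = 3.32e-12, and adjusted p = 0.644 with an estimated correlation). Without Vehicle 3, the library with the most ribosomal RNA, that median was 0.61. FOXO targets, which PI3K signalling represses, did not pass as a list (median 0.03, adjusted p = 0.522). CITED2 had a change of 0.70 ± 0.235 and PIK3IP1, a negative regulator of PI3K, 0.78 ± 0.27 (adjusted p = 0.21 and 0.211). Also not passing were cholesterol synthesis (median 0.27, adjusted p = 0.353), ERK pathway output (0.34, 0.353), mesenchymal transition (0.24, 0.353), hypoxia response (0.30, 0.361), inflammatory chemokines (0.24, 0.361) and carry-over from host cells (0.16, 0.361). The same held for luminal urothelial (0.16, 0.415), fatty acid synthesis (-0.02, 0.523), cell cycle (-0.03, 0.523), unfolded protein response (-0.12, 0.714), receptor tyrosine kinases (-0.08, 0.776) and the integrated stress response (0.14, 0.865). Without Vehicle 3, MHC class I no longer passed (median 0.25, adjusted p = 0.0747), while FOXO targets (0.22, 0.0407), hypoxia response (0.36, 0.0121), ERK pathway output (0.42, 0.0113), mesenchymal transition (0.24, 0.00745) and host carry-over (0.31, 0.0171) did. With each library left out in turn at the preset correlation, added after the data were seen, the squamous and ribosomal protein calls held in 8 of 8 fits. Basal urothelial and angiogenic ligand genes no longer passed without Vehicle 2 (adjusted p = 0.115 for both). Glycolysis was lost in 2 fits (highest adjusted p = 0.413), MHC class I in 4 (0.207) and interferon response in 5 (0.616 without Vehicle 2, with a median of 0.06). Of the drug targets, PIK3CB had a change of -0.70 ± 0.26 (adjusted p = 0.224) and PIK3CA -0.41 ± 0.32 (adjusted p = 0.463). By limma 0 human genes passed, with 2707 at an unadjusted p under 0.05. Counts were 0 by edgeR, 0 by voom and 173 by DESeq2 (165 higher, 8 lower), where independent filtering left 1008 of 14533 genes with an adjusted p.

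Among host genes, the adipocyte list was lower after alpelisib, with all 8 members negative and a median of -1.63 (adjusted p = 0.00724), and so was the skeletal muscle list (15 of 15 negative, median -1.91, adjusted p = 0.0413), with 0 genes adjusted over either list alone. The macrophage list fell with a median of -0.07 (11 of 20 negative, 3 lower adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.892 with an estimated correlation for all 3 lists). Emr1, the macrophage marker F4/80, had a change of -1.08 ± 0.19 (adjusted p = 0.183), from 868 ± 142 to 410.0 ± 63.5, and the integrin Itgam -0.93 ± 0.25 (adjusted p = 0.256). The keratin list of tumour carry-over and skin rose with a median of 0.78 (15 of 17 positive, 4 higher adjusted over the list alone, adjusted p = 0.00404, and adjusted p = 0.892 with an estimated correlation). Its genes had more human than mouse reads in 17 of 17 cases, and without Vehicle 3 its median was 0.00. Ribosomal proteins rose with a median of 0.89 (25 of 25 positive, 8 higher adjusted over the list alone, adjusted p = 9.87e-14, and adjusted p = 0.892 with an estimated correlation), and with 0.37 without Vehicle 3. With each library left out in turn, ribosomal proteins held in 8 of 8 fits. The adipocyte call was lost without Vehicle 4 (adjusted p = 0.108) and the keratin call without Alpelisib 1 (adjusted p = 0.46). The macrophage and skeletal muscle calls were lost in 5 of 8 fits each, with medians of -0.01 without Alpelisib 1 (adjusted p = 0.278) and -0.43 without Vehicle 1 (0.695).

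The vessel lists did not pass after alpelisib alone: endothelial genes had a median of -0.08 (adjusted p = 0.14), tip endothelial genes -0.18 (0.783) and pericyte genes 0.25 (0.314). Other lists that did not pass were fibroblast and matrix (0.15, 0.677), neutrophil (0.07, 0.855), natural killer (-0.56, 0.14), T cell (-0.73, 0.301), dendritic cell (-0.01, 0.855), mast cell (0.34, 0.413), interferon response (0.16, 0.557), cell cycle (-0.16, 0.0816), hypoxia response (0.04, 0.202), FOXO targets (-0.09, 0.924), nintedanib target receptors (0.08, 0.855) and inflammatory chemokines (0.03, 0.855). For the dendritic cell and target receptor lists the sign of the median differed from that of the mean or the test. Without Vehicle 3, fibroblast (0.30, adjusted p = 0.00147), cell cycle (-0.18, 0.0259) and hypoxia genes (0.19, 0.00833) passed. The VEGF receptor gene Kdr had a change of -0.77 ± 0.42 (adjusted p = 0.506). By limma 0 mouse genes passed, with 1249 at an unadjusted p under 0.05. Counts were 0 by edgeR, 0 by voom and 113 by DESeq2 (91 higher, 22 lower), which gave 2645 of 11831 genes an adjusted p.

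Nintedanib against vehicle asks what the receptor inhibitor did alone in tumours called resistant to it, first in tumour cells. Squamous genes rose as a group with a median of 1.31 (20 of 22 positive, 13 higher adjusted over the list alone, adjusted p = 8.52e-13, and adjusted p = 0.551 with an estimated correlation). KRTDAP had a change of 2.14 ± 0.52 and KRT10, a keratin of differentiating layers, 1.06 ± 0.29 (adjusted p = 0.619 for both). Cell cycle genes fell with a median of -0.23 (23 of 30 negative, adjusted p = 0.00036, and adjusted p = 0.551 with an estimated correlation). The mitotic checkpoint kinase BUB1B had a change of -0.77 ± 0.26 and the topoisomerase TOP2A -0.98 ± 0.39. Basal urothelial genes rose (0.40, adjusted p = 0.00108), as did mesenchymal genes (0.37, adjusted p = 0.00378), among which the receptor AXL had a change of 0.92 ± 0.30, and angiogenic ligands (0.46, adjusted p = 0.00601). These 3 calls were lost (adjusted p = 0.551 with an estimated correlation). MHC class I and interferon response genes rose with medians of 0.34 and 0.14 (adjusted p = 0.0318 for both), and glycolysis genes with 0.19 (adjusted p = 0.0431). They had an adjusted p = 0.551 with an estimated correlation, and glycolysis 0.717. FOXO targets fell with a median of -0.21 (13 of 19 negative, adjusted p = 0.0431) and fatty acid synthesis genes with -0.24 (11 of 12 negative, adjusted p = 0.0442), and both calls were lost (adjusted p = 0.551 with an estimated correlation). Ribosomal proteins rose with 0.76 (25 of 25 positive, adjusted p = 9.96e-12, and adjusted p = 0.551 with an estimated correlation), and with 0.27 without Vehicle 3. Adjusted over the list alone, 0 genes passed in the lists other than the squamous one.

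Not passing in tumour cells after nintedanib were cholesterol synthesis (median 0.04, adjusted p = 0.633), hypoxia response (0.12, 0.737), ERK pathway output (0.14, 0.633), luminal urothelial (0.01, 0.746, with a test direction opposite to its median), and receptor tyrosine kinases (-0.09, 0.633). The same held for the integrated stress response (0.09, 0.361), the unfolded protein response (-0.03, 0.704), inflammatory chemokines (0.32, 0.0966) and host carry-over (0.41, 0.0577). Without Vehicle 3, FOXO targets (-0.05, adjusted p = 0.635), fatty acid synthesis (-0.10, 0.452) and MHC class I (0.12, 0.159) no longer passed, and hypoxia response (0.23, 0.0227), ERK output (0.13, 0.0205), chemokines (0.12, 0.0148) and host carry-over (0.57, 0.000125) did. With each library left out in turn, the squamous, ribosomal protein and cell cycle calls held in 9 of 9 fits. Basal urothelial (adjusted p = 0.262) and angiogenic ligand genes (0.237) no longer passed without Vehicle 2. Calls were lost in 2 fits for mesenchymal transition (highest adjusted p = 0.128), 3 for glycolysis (0.885) and interferon response (0.435), whose medians turned to -0.0033 and -0.03 without Vehicle 2, 4 for MHC class I (0.159) and 5 for FOXO targets (0.635) and fatty acid synthesis (0.452). The FGF receptor genes FGFR1, FGFR2 and FGFR3 had changes of 0.145 ± 0.22, -0.25 ± 0.26 and 0.16 ± 0.24. By limma 0 human genes passed, with 1035 at an unadjusted p under 0.05, against 0 by edgeR, 0 by voom and 13 by DESeq2 (13 higher, 0 lower), which gave 1008 genes an adjusted p. The limma count was 1 without nintedanib non-responder 1.

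In the host, nintedanib lowered vessel genes. The endothelial list fell with a median of -0.79, and all 25 measured members were negative (2 lower over all genes, 13 lower adjusted over the list alone, camera adjusted p = 2.8e-18, and adjusted p = 0.0571 with an estimated correlation). Flt4, the VEGF receptor 3 and a target of the drug, fell by 2.09 ± 0.34 on the log2 scale (adjusted p = 0.0113), from 150.0 ± 84.2 to 32 ± 9.79 normalized counts, and Mmrn2, an endothelial matrix glycoprotein, by 1.54 ± 0.30 (adjusted p = 0.0466). The angiogenic and tip endothelial list fell with a median of -0.74 (18 of 20 negative, 2 lower over all genes, 13 lower adjusted over the list alone, adjusted p = 2.54e-14, and adjusted p = 0.0571 with an estimated correlation). In it, Dll4, the Notch ligand of tip cells, fell by 1.91 ± 0.30 (adjusted p = 0.0113, from 211 ± 41.7 to 55.4 ± 11.7), and Apln, a peptide made by tip cells, fell by 2.05 ± 0.40 (adjusted p = 0.0466, from 479 ± 105 to 118 ± 36.1). Endothelial genes had more mouse than human reads in 23 of 25 cases and tip genes in 15 of 20. The receptor genes Kdr (-1.22 ± 0.40, adjusted p = 0.382) and Flt1 (-1.26 ± 0.35, adjusted p = 0.24) did not pass alone, nor did Pdgfra (0.46 ± 0.36), Pdgfrb (0.23 ± 0.28) and Fgfr1 (0.41 ± 0.23).

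The largest decreases after nintedanib were in Clca5 (-3.01 ± 0.39, adjusted p = 0.00269, from 77.5 ± 61.3 to 6.94 ± 1.70), the potassium channel gene Kcnj2 (-2.54 ± 0.44, adjusted p = 0.0205) and the endothelial early-response gene Apold1 (-2.49 ± 0.33, adjusted p = 0.00269). They were followed by nestin (Nes, -2.47 ± 0.40, adjusted p = 0.0113), Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (-2.15 ± 0.42, adjusted p = 0.0466), and Trp53i11 (-2.15 ± 0.29, adjusted p = 0.00269). C1s, a complement protease, rose by 1.30 ± 0.25 (adjusted p = 0.0466, from 485 ± 124 to 1229 ± 410). The mouse cell cycle list fell with a median of -0.64 (27 of 30 negative, 1 lower over all genes, 10 lower adjusted over the list alone, adjusted p = 4.8e-12, and adjusted p = 0.0571 with an estimated correlation). Its mitotic kinesin Kif20a fell by 1.56 ± 0.25 (adjusted p = 0.0113). However, all 30 of these genes had more human than mouse reads. Of 11831 mouse genes, 1 was higher and 17 were lower, with 1002 at an unadjusted p under 0.05, against 20 by edgeR and 93 by DESeq2. Leaving out 1 library gave 4 genes without Vehicle 1, 9 without Vehicle 2, 8 without responder 1 and 26 without non-responder 1, and other libraries 12 to 14.

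Mast cell genes rose after nintedanib with a median of 1.60 (5 of 6 positive, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00951, and adjusted p = 0.534 with an estimated correlation). The tryptase gene Tpsb2 had a change of 2.85 ± 0.78 (adjusted p = 0.236). Inflammatory chemokines rose (0.52, 18 of 20 positive, adjusted p = 0.00293), as did natural killer genes (0.73, 12 of 12 positive, adjusted p = 0.0277). These had an adjusted p = 0.534 and 0.664 with an estimated correlation. Also higher were adipocyte genes (0.96, 8 of 8 positive, adjusted p = 0.0277), hypoxia response genes (0.16, 15 of 22 positive, adjusted p = 0.0328) and ribosomal proteins (0.57, 25 of 25 positive, adjusted p = 8.15e-08), with 0 adjusted over each list alone. These had an adjusted p = 0.534, 0.664 and 0.534 with an estimated correlation. The list of receptors that nintedanib targets fell (-0.43, 5 of 8 negative, 1 lower over all genes, 3 lower adjusted over the list alone, adjusted p = 0.0277, and adjusted p = 0.534 with an estimated correlation). So did skeletal muscle genes (-1.33, 13 of 15 negative, 0 adjusted over the list alone, adjusted p = 0.0314, and adjusted p = 0.707 with an estimated correlation). Without Vehicle 3 the ribosomal protein median was 0.20. Adipocyte (-0.03, adjusted p = 0.181) and target receptor genes (-0.53, 0.201) no longer passed, and fibroblast (0.47, 1.53e-06) and neutrophil genes (0.38, 0.00852) did. With each library left out in turn, the endothelial, tip endothelial, cell cycle and ribosomal protein calls held in 9 of 9 fits, and the other 7 did not. Natural killer scores (mean log2 level of the list) of 7.02 in non-responder 2 and 6.231 in responder 1 stood above vehicle (3.351 to 5.46), and the other 3 nintedanib libraries lay within it (3.508 to 4.535). The call was lost without either of these 2 libraries (adjusted p = 0.365 and 0.137). Adipocyte scores were high in the 2 non-responders (7.814 and 8.215), while responders had a mean of 4.168 against 4.722 in vehicle, and the call was lost without either non-responder (adjusted p = 0.237 and 0.365). The mast cell call was lost without Vehicle 2 (adjusted p = 0.197), and the chemokine call without Vehicle 1 or responder 1 (highest adjusted p = 0.0842). Target receptors were lost in 4 fits (0.201), hypoxia response in 5 (0.442) and skeletal muscle in 6 (0.782 without Vehicle 1, with a median of -0.08). Lists that did not pass were pericyte (0.04, adjusted p = 0.595, with a negative mean and test), fibroblast (0.22, 0.091), macrophage (0.34, 0.394), neutrophil (0.27, 0.102), T cell (0.40, 0.771), dendritic cell (0.39, 0.101), the keratin list (-0.31, 0.638), interferon response (0.16, 0.0912) and FOXO targets (-0.13, 0.294).

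**Figure D2:**
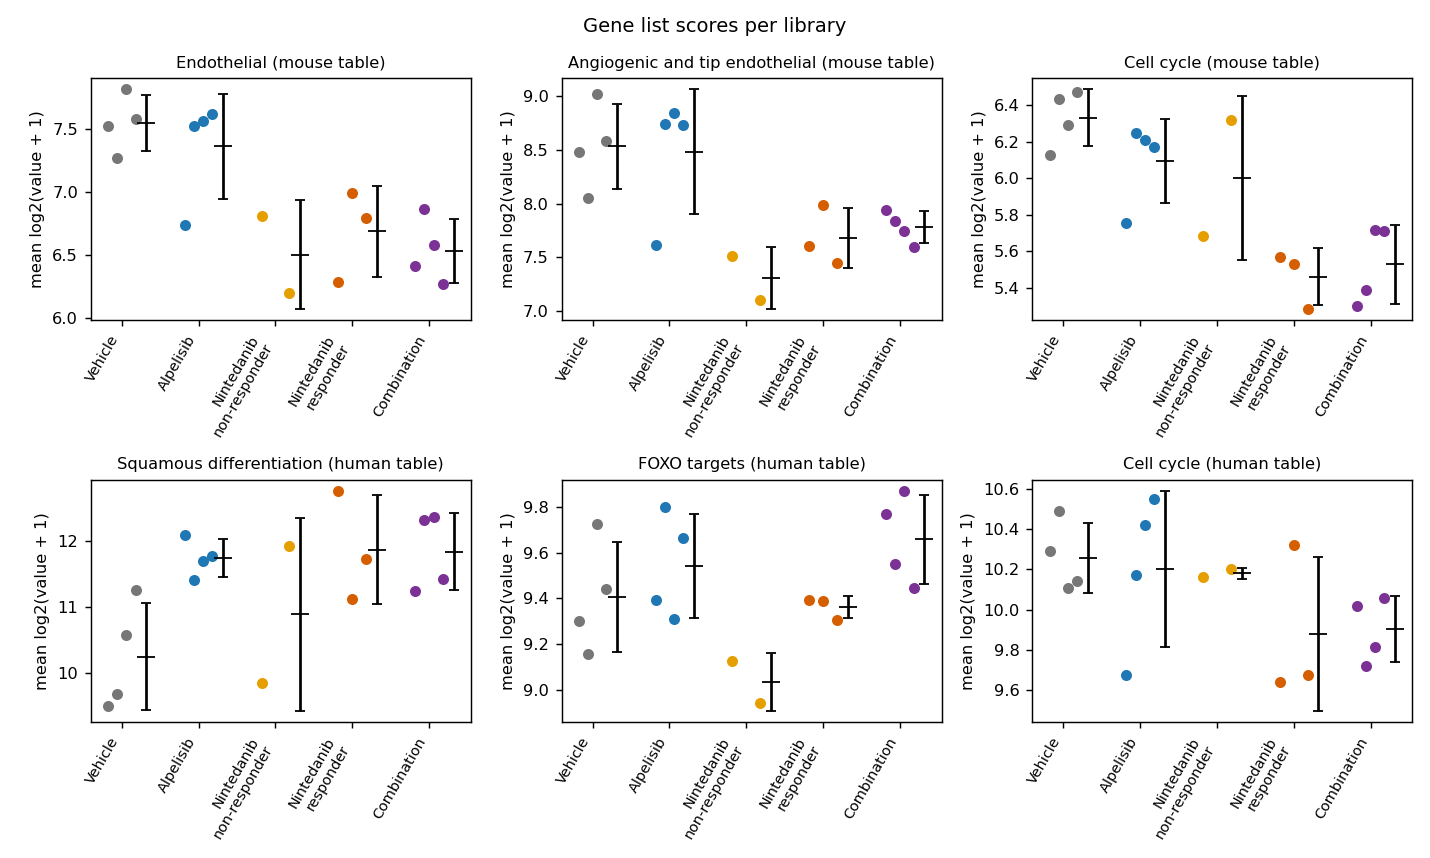
Scores of 6 gene lists, each the mean log2 normalized count of a list in 1 library (points), by group, with black marks for the mean ± SD. The mouse endothelial score was 7.55 ± 0.224 in vehicle, 6.62 ± 0.351 in nintedanib and 6.54 ± 0.255 in combination tumours.

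The combination against vehicle asks what both drugs together did. In tumour cells, squamous genes rose with a median of 1.59 (21 of 22 positive, 2 higher over all genes, 15 higher adjusted over the list alone, adjusted p = 6.8e-13, and adjusted p = 0.521 with an estimated correlation). KRTDAP rose by 2.98 ± 0.54 (adjusted p = 0.0361), from 1748 ± 1080 to 12760 ± 4030 normalized counts, and SPRR1B, a cornified envelope precursor, by 2.19 ± 0.47 (adjusted p = 0.0499). Basal urothelial genes rose with a median of 0.84 (17 of 17 positive, 1 higher over all genes, 8 higher adjusted over the list alone, adjusted p = 6.72e-07, and adjusted p = 0.521 with an estimated correlation). The keratin KRT16 rose by 2.19 ± 0.46 (adjusted p = 0.0485). Cell cycle genes fell with a median of -0.45 (24 of 30 negative, 4 lower adjusted over the list alone, adjusted p = 7.09e-05, and adjusted p = 0.59 with an estimated correlation). The mitotic kinase AURKA had a change of -0.96 ± 0.21 (adjusted p = 0.06). Besides squamous genes, the largest increases were in SLURP1, a secreted epidermal protein (3.12 ± 0.60, adjusted p = 0.0361, from 64.9 ± 68.2 to 489 ± 304), SLAMF9 (2.81 ± 0.52), slow troponin T (TNNT1, 2.70 ± 0.51) and cytidine deaminase (CDA, 2.66 ± 0.44, adjusted p = 0.0271). The beta-globin gene HBB, on the list of carry-over from host cells, rose by 3.81 ± 0.74 (adjusted p = 0.0374) at a level of 53.3 ± 28.6. The largest decreases were in PIGR, the polymeric immunoglobulin receptor (-2.47 ± 0.46, adjusted p = 0.0361, from 1052 ± 473 to 177 ± 48.5) and the matrix gene NPNT (-1.17 ± 0.25, adjusted p = 0.0499). Lower too were PIK3R3, a regulatory subunit of PI3K (-1.04 ± 0.20, adjusted p = 0.0361), the spindle gene FAM83D (-1.01 ± 0.21, adjusted p = 0.043) and FAM84B (-0.97 ± 0.17, adjusted p = 0.0271).

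Further human lists rose with the combination. They were glycolysis (0.38, 19 of 20 positive, 6 higher adjusted over the list alone, adjusted p = 4.9e-05), with the aldolase ALDOA at 1.18 ± 0.27 (adjusted p = 0.0744), and angiogenic ligands (0.68, 13 of 16 positive, 6 higher adjusted over the list alone, adjusted p = 0.00378). These had an adjusted p = 0.59 and 0.521 with an estimated correlation. Mesenchymal transition (0.37, 17 of 22 positive, 2 higher adjusted over the list alone, adjusted p = 0.00311) and interferon response genes (0.27, 22 of 28 positive, 3 higher adjusted over the list alone, adjusted p = 0.00378) rose as well (both adjusted p = 0.59 with an estimated correlation). The remaining lists were hypoxia response (0.26, 17 of 22 positive, 2 higher adjusted over the list alone, adjusted p = 0.0248), MHC class I (0.55, 9 of 12 positive, 0 adjusted over the list alone, adjusted p = 0.0248) and ribosomal proteins (1.15, 25 of 25 positive, 24 higher adjusted over the list alone, adjusted p = 1.41e-14). These 3 calls were lost (adjusted p = 0.521 to 0.595 with an estimated correlation). FOXO targets did not pass (0.21, adjusted p = 0.139, with 4 higher and 1 lower adjusted over the list alone). CITED2 had a change of 0.93 ± 0.235 (adjusted p = 0.0973) and PDK4, a brake on glucose oxidation, 1.52 ± 0.535 (adjusted p = 0.161). Also not passing were cholesterol synthesis (-0.06, adjusted p = 0.93), fatty acid synthesis (-0.16, 0.156), ERK pathway output (-0.03, 0.766), luminal urothelial (0.20, 0.273), receptor tyrosine kinases (0.08, 0.93), the integrated stress response (-0.07, 0.978), the unfolded protein response (-0.07, 0.93), chemokines (-0.06, 0.93) and host carry-over (0.14, 0.152). For 5 of these lists, cholesterol, ERK, both stress responses and chemokines, the mean had the opposite sign to the median. Within the chemokines, CCL5 rose by 1.66 ± 0.35 (adjusted p = 0.0484).

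Of 14533 human genes, 46 were higher and 6 lower with the combination, with 2624 at an unadjusted p under 0.05. The count was 0 without any 1 of Vehicle 1, Vehicle 2, Vehicle 3, Combination 2, Combination 3 or Combination 4, and 97 without Combination 1. With each library left out in turn, the squamous, basal urothelial, ribosomal protein, glycolysis and cell cycle calls held in 8 of 8 fits. Angiogenic ligands were lost without Vehicle 2 (adjusted p = 0.0644), mesenchymal transition and interferon response in 2 fits each (highest adjusted p = 0.102 and 0.0932), and hypoxia response and MHC class I in 3 each. The hypoxia median turned to -0.01 without Vehicle 2 (adjusted p = 0.784), and MHC class I had 0.37 without Combination 2 (0.315). Without the 4 libraries rich in ribosomal RNA the gene count was also 0, a fit added after the data were seen. Without Vehicle 3 the top genes had adjusted p-values from 0.052 to 0.068, the ribosomal protein median was 0.65, MHC class I no longer passed (0.29, adjusted p = 0.104), and FOXO targets (0.24, 0.00456) and host carry-over (0.44, 0.00825) did.

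Among mouse reads, the combination lowered endothelial genes (median -1.04, 25 of 25 negative, 4 lower over all genes, 16 lower adjusted over the list alone, adjusted p = 2.02e-14, and adjusted p = 0.133 with an estimated correlation). Flt4 fell by 1.95 ± 0.36 (adjusted p = 0.0216), the endothelial cadherin Cdh5 by 1.58 ± 0.35 (adjusted p = 0.0415) and Pecam1, which encodes CD31, by 1.19 ± 0.27 (adjusted p = 0.0433). Tip endothelial genes fell (-0.86, 17 of 20 negative, 3 lower over all genes, 2 higher and 12 lower adjusted over the list alone, adjusted p = 1.74e-06, and adjusted p = 0.273 with an estimated correlation). Apln fell by 2.56 ± 0.42 (adjusted p = 0.0126, from 479 ± 105 to 82.6 ± 28.4) and Dll4 by 1.40 ± 0.32 (adjusted p = 0.0452). Cell cycle genes fell (-0.76, 28 of 30 negative, 3 lower over all genes, 1 higher and 14 lower adjusted over the list alone, adjusted p = 1.91e-12, and adjusted p = 0.0921 with an estimated correlation). Kif20a fell by 1.80 ± 0.27, Ccna2 by 1.53 ± 0.30 and Ccnb1 by 1.67 ± 0.34. Hypoxia response genes rose (0.56, 19 of 22 positive, 3 higher over all genes, 8 higher adjusted over the list alone, adjusted p = 6.82e-07, and adjusted p = 0.273 with an estimated correlation). Ndrg1 rose by 1.65 ± 0.31, P4ha2 by 1.09 ± 0.21 and Fam162a by 1.5 ± 0.33. Of cell cycle and hypoxia genes, 0 of 30 and 0 of 21 had more mouse than human reads. Carry-over was not tested here or in later contrasts, so host origin stays open. Fibroblast and matrix genes rose (0.56, 21 of 24 positive, 2 higher adjusted over the list alone, adjusted p = 0.000394, and adjusted p = 0.633 with an estimated correlation). All 6 list calls held at the preset correlation in 8 of 8 fits with 1 library left out. Ribosomal proteins rose with a median of 1.05 (20 higher adjusted over the list alone, adjusted p = 2.45e-14, and adjusted p = 0.273 with an estimated correlation), and with 0.63 without Vehicle 3.

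The largest host increases with the combination were in the steroid sulfate transporter gene Slc10a6 (2.78 ± 0.48, adjusted p = 0.0132), the hypoxia-induced gene Ndufa4l2 (2.49 ± 0.42, adjusted p = 0.0127, from 62.4 ± 22.2 to 372 ± 175) and Crabp1, a retinoic acid binding protein (2.21 ± 0.30, adjusted p = 0.00562, from 278 ± 38.0 to 1292 ± 253). Next came metallothionein Mt1 (2.08 ± 0.42), the transcription factor gene Twist2 (1.84 ± 0.37) and the immediate early gene Ier3 (1.80 ± 0.34). The largest decreases, besides Apln, were in Apold1 (-2.53 ± 0.35, adjusted p = 0.00562), the potassium channel subunit gene Kcne3 (-2.52 ± 0.56, adjusted p = 0.0416), Clca5 (-2.50 ± 0.41), Spry4 (-2.49 ± 0.44) and cholesterol 25-hydroxylase (Ch25h, -2.33 ± 0.45). The keratins Krt17 (1.76 ± 0.29), Krt19 (1.56 ± 0.31) and Krt14 (1.69 ± 0.37) rose on a list that did not pass (median 0.14, adjusted p = 0.054). Mouse reads per human read were 0.144 for Krt17, 0.035 for Ndufa4l2, 0.015 for Ndrg1 and 0.0375 for Kif20a, against 2.67 for Flt4, 73.9 for Pecam1 and 1713 for Cdh5. Target receptor genes Kdr (-1.59 ± 0.42) and Flt1 (-1.37 ± 0.37) had an adjusted p of 0.0774 each.

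Mouse lists that did not pass with the combination were pericyte (-0.14, adjusted p = 0.648, with a positive mean and test), macrophage (0.30, 0.126), neutrophil (0.16, 0.31), natural killer (-0.84, 0.072), T cell (-0.99, 0.129), dendritic cell (0.20, 0.942), mast cell (1.16, 0.126), adipocyte (-1.19, 0.0782), and skeletal muscle (-1.53, 0.126). The same held for interferon response (-0.13, 0.0673), FOXO targets (0.20, 0.14), target receptors (-0.29, 0.129) and chemokines (0.30, 0.648). Without Vehicle 3, mast cell (1.48, adjusted p = 0.0434), adipocyte (-1.84, 0.00268), skeletal muscle (-2.84, 0.0015), interferon response (-0.21, 0.0177) and FOXO genes (0.25, 0.00821) passed. Of 11831 mouse genes, 47 were higher and 45 lower, with 1957 at an unadjusted p under 0.05. Leaving out 1 library gave 18 genes without Vehicle 4, 19 without Combination 3, 5 without Combination 4, 41, 44 and 45 without Vehicle 1, Vehicle 2 and Combination 2, and 106 without Combination 1. Without the 4 libraries rich in ribosomal RNA 22 genes passed (18 higher, 4 lower).

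**Figure D3:**
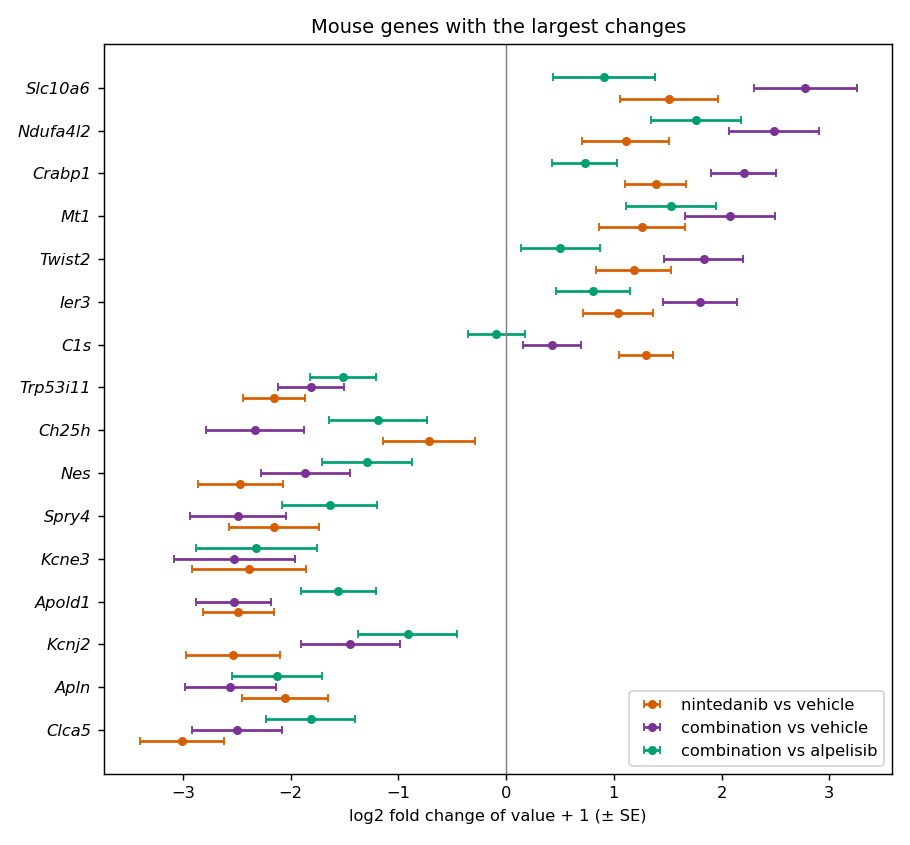
Log2 fold changes ± SE of the 16 mouse genes named as largest increases or decreases, for nintedanib and the combination against vehicle and for the combination against alpelisib. Apln had changes of -2.05, -2.56 and -2.13 in these contrasts.

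The combination against alpelisib asks what nintedanib added to alpelisib. Among mouse reads, endothelial genes fell (median -0.85, 24 of 25 negative, 13 lower adjusted over the list alone, adjusted p = 5.06e-18, and adjusted p = 0.0696 with an estimated correlation). Tip endothelial genes fell with -0.76 (16 of 20 negative, 9 lower adjusted over the list alone, adjusted p = 1.08e-09, and adjusted p = 0.131 with an estimated correlation), and cell cycle genes with -0.51 (26 of 30 negative, 9 lower adjusted over the list alone, adjusted p = 2.24e-13, and adjusted p = 0.0687 with an estimated correlation). Apln had a change of -2.13 ± 0.42 and the vessel-destabilising ligand gene Angpt2 -1.51 ± 0.34 (adjusted p = 0.311 for both). Macrophage genes rose with a median of 0.64 (17 of 20 positive, 0 adjusted over the list alone, adjusted p = 6.84e-08, and adjusted p = 0.131 with an estimated correlation). Cd68 had a change of 0.69 ± 0.24 and the mannose receptor gene Mrc1 of 1.14 ± 0.455. Hypoxia response genes rose (0.53, 19 of 22 positive, 1 higher adjusted over the list alone, adjusted p = 9.68e-08, and adjusted p = 0.14 with an estimated correlation). So did fibroblast genes (0.35, 23 of 24 positive, 0 adjusted over the list alone, adjusted p = 3.54e-05, and adjusted p = 0.54 with an estimated correlation). Interferon response genes fell (-0.28, 21 of 25 negative, 0 adjusted over the list alone, adjusted p = 0.000111, and adjusted p = 0.273 with an estimated correlation). The fibroblast call was lost without Alpelisib 1 (median 0.04, adjusted p = 0.422), and the other 6 calls held in 8 of 8 fits with 1 library left out. Without Vehicle 3, which this contrast uses only for the spread, target receptor genes passed (-0.36, adjusted p = 0.0497).

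In tumour cells, cell cycle genes fell against alpelisib with a median of -0.31 (27 of 30 negative, adjusted p = 1.41e-06), as did ERK pathway output (-0.25, 15 of 19 negative, adjusted p = 0.0217), with the immediate early gene FOS at -0.94 ± 0.34. Mesenchymal genes rose (0.22, 19 of 22 positive, adjusted p = 0.0217, and adjusted p = 0.979 with an estimated correlation for all 3). The protease gene MMP9 had a change of 2.20 ± 0.72, with 63.8 mouse reads per human read, which host carry-over can explain. Adjusted over these lists alone 0 genes passed. The cell cycle call held in 8 of 8 fits with 1 library left out, and was lost in 3 for ERK output (highest adjusted p = 0.211) and 4 for mesenchymal genes (0.338 without Combination 1, with a median of 0.04). Over all genes limma called 1 mouse gene, D930048N14Rik, named here after its values were seen because it falls outside the rule for named genes. It fell by 2.51 ± 0.38 (adjusted p = 0.041), from 28.4 ± 0.948 to 4.28 ± 1.23 normalized counts. Without Alpelisib 1 the mouse count was 13, and 0 without any other 1 of these 8 libraries. In human 0 genes passed by limma, with 648 at an unadjusted p under 0.05, and 0 by edgeR, voom and DESeq2.

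The combination against nintedanib asks what alpelisib added to nintedanib. In tumour cells, FOXO targets rose with a median of 0.29 (15 of 19 positive, 4 higher adjusted over the list alone, adjusted p = 2.15e-06, and adjusted p = 0.38 with an estimated correlation). PDK4 had a change of 2.70 ± 0.51 (adjusted p = 0.676, from 11.3 ± 7.98 to 67.3 ± 25.8), CITED2 0.83 ± 0.22, PIK3IP1 0.81 ± 0.26 and the ubiquitin ligase gene FBXO32 0.72 ± 0.20 (adjusted p = 0.988 for each). Ribosomal proteins (0.38, adjusted p = 2e-05), basal urothelial genes (0.42, 17 of 17 positive, adjusted p = 5.89e-05), glycolysis (0.25, adjusted p = 5.89e-05), hypoxia response (0.26, adjusted p = 0.00135) and squamous genes (0.34, adjusted p = 0.00431) rose, with 0 adjusted over each list alone, and these calls were lost (adjusted p = 0.722 with an estimated correlation). FOXO targets, ribosomal proteins and glycolysis held in 9 of 9 fits with 1 library left out. Without non-responder 1, basal urothelial (adjusted p = 0.0519) and hypoxia genes (0.0583) no longer passed, and the squamous median fell to 0.01 (0.991). The score of that library was 9.854, against 11.12 to 12.75 in the other nintedanib libraries. The squamous call was lost in 4 fits. Without Vehicle 3 luminal genes passed (0.23, adjusted p = 0.0452). By limma 0 human genes passed, with 556 at an unadjusted p under 0.05, against 0 by edgeR, 0 by voom and 1 by DESeq2.

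In the host, interferon genes were lower with the combination than with nintedanib alone, and lymphocyte genes mainly against 2 of the 5 nintedanib libraries. Natural killer genes fell with a median of -1.65 (12 of 12 negative, 0 adjusted over the list alone, adjusted p = 4.04e-07, and adjusted p = 0.311 with an estimated correlation), with the receptor gene Ncr1 at -1.73 ± 0.60. T cell genes fell with -1.65 (6 of 7 negative, 0 adjusted over the list alone, adjusted p = 0.0225, and adjusted p = 0.491 with an estimated correlation). Non-responder 2 and responder 1 had natural killer scores of 7.02 and 6.231 and T cell scores of 6.687 and 5.972. Responder 3 (4.535 and 4.037) lay above the combination (3.004 to 3.89 and 2.127 to 3.953), and the other 2 libraries within it. The T cell call was lost in 5 of 9 fits with 1 library left out (highest adjusted p = 0.184), and the natural killer call in 0. Interferon response genes fell (-0.30, 24 of 25 negative, 1 lower adjusted over the list alone, adjusted p = 1.25e-06, and adjusted p = 0.311 with an estimated correlation). So did chemokines (-0.46, 12 of 20 negative, 2 lower adjusted over the list alone, adjusted p = 0.00972, and adjusted p = 0.491 with an estimated correlation). The cytokine gene Tnf had a change of -1.59 ± 0.34 and the interferon-induced chemokine gene Cxcl10 -2.22 ± 0.53 (adjusted p = 0.4 for both). Mouse reads per human read were 1.655 for Tnf and 0.0823 for Cxcl10. Adipocyte genes fell with -2.29 (8 of 8 negative, 6 lower adjusted over the list alone, adjusted p = 8e-07, and adjusted p = 0.307 with an estimated correlation). This rested on the 2 non-responders (scores 7.814 and 8.215), as 2 responders (2.977 and 3.724) lay within the combination range (2.112 to 5.583) and responder 3 (5.803) just above it. Cell cycle genes fell with -0.19 (adjusted p = 0.0272, and adjusted p = 0.491 with an estimated correlation). FOXO targets rose (0.31, 16 of 20 positive, 2 higher adjusted over the list alone, adjusted p = 0.00189, and adjusted p = 0.355 with an estimated correlation), with Cited2 at 1.18 ± 0.26. Also rising were hypoxia response (0.44, adjusted p = 1.25e-06) and ribosomal proteins (0.49, adjusted p = 1.1e-06). The same held for the keratin list (0.54, 3 higher adjusted over the list alone, adjusted p = 0.000104), fibroblast (0.27, adjusted p = 0.00298) and tip endothelial genes (0.13, 12 of 20 positive, adjusted p = 0.0459), with calls lost (adjusted p = 0.311 to 0.571 with an estimated correlation). With 1 library left out, FOXO targets were lost without Combination 1 (adjusted p = 0.0553), chemokines and fibroblast genes in 2 fits each (highest adjusted p = 0.236 and 0.188), cell cycle genes in 3 and tip endothelial genes in 5. Without non-responder 2 these last medians were -0.06 (adjusted p = 0.666) and -0.02 (0.337). By limma 0 mouse genes passed, with 830 at an unadjusted p under 0.05, against 0 by edgeR, 0 by voom and 30 by DESeq2 (17 higher, 13 lower). Without Combination 1 the limma count was 4.

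Responders against non-responders asks how nintedanib tumours that the titles separate differed, with 3 and 2 libraries. The series description gives the numbers the other way round, and if the names were swapped, every sign below would turn. In the host, adipocyte genes were lower in responders with a median of -4.66 (8 of 8 negative, 7 lower adjusted over the list alone, camera adjusted p = 2.92e-15, and adjusted p = 0.0189 with an estimated correlation), with Adipoq, an adipocyte hormone gene, at -5.58 ± 1.53. Skeletal muscle genes were lower (-4.22, 15 of 15 negative, adjusted p = 1.44e-09, and adjusted p = 0.292 with an estimated correlation), and cell cycle genes (-0.43, 30 of 30 negative, adjusted p = 1.55e-09, and adjusted p = 0.108 with an estimated correlation). Non-responder 1 alone carried the skeletal muscle difference: its score was 10.6, against 2.337 in non-responder 2 and 1.738 to 3.631 in responders, and without it the median was 0.25 (adjusted p = 0.516). Cell cycle genes no longer passed without non-responder 2 (-0.10, adjusted p = 0.0748). Fibroblast genes were higher (0.61, 22 of 24 positive, adjusted p = 1.99e-09, and adjusted p = 0.292 with an estimated correlation), with the collagen gene Col6a2 at 1.07 ± 0.39. Higher too were hypoxia response (0.35, adjusted p = 2.5e-06), tip endothelial (0.47, adjusted p = 0.000381), target receptor (0.37, adjusted p = 0.00117) and endothelial genes (0.22, adjusted p = 0.0284). These had an adjusted p = 0.292, 0.435, 0.292 and 0.644 with an estimated correlation. Ribosomal proteins were lower (-0.35, adjusted p = 0.00131, and adjusted p = 0.644 with an estimated correlation). Tip endothelial genes no longer passed without non-responder 2 (adjusted p = 0.204), ribosomal proteins were lost in 2 of 5 fits with 1 library left out (-0.10 without responder 3, adjusted p = 0.257) and endothelial genes in 3 (-0.17 without non-responder 2, 0.457, and 0.03 without responder 2, 0.585). Of single genes, 0 passed adjusted over a list alone outside the adipocyte list.

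In tumour cells, responders had higher hypoxia response genes (0.52, 22 of 22 positive, adjusted p = 9.72e-10) and squamous genes (1.0, 19 of 22 positive, 1 higher adjusted over the list alone, adjusted p = 6.92e-09), with the late cornified envelope gene LCE3D at 4.04 ± 0.98. Both calls were lost (adjusted p = 0.253 and 0.304 with an estimated correlation). Glycolysis genes were higher (0.41, adjusted p = 4.01e-07, and adjusted p = 0.304 with an estimated correlation), with the hexokinase HK2 at 1.78 ± 0.65. Also higher were ERK pathway output (0.30, adjusted p = 2.48e-06), chemokines (0.60, adjusted p = 2.48e-06), FOXO targets (0.31, adjusted p = 2.42e-05), basal urothelial (0.44, adjusted p = 3.49e-05), host carry-over (0.71, adjusted p = 0.000314), mesenchymal (0.17, adjusted p = 0.000753) and angiogenic ligand genes (0.25, adjusted p = 0.0281). These calls were lost (adjusted p = 0.253 to 0.352 with an estimated correlation). Cell cycle genes were lower (-0.26, 29 of 30 negative, adjusted p = 6.59e-06, and adjusted p = 0.352 with an estimated correlation). Only the hypoxia and FOXO calls held in 5 of 5 fits with 1 library left out. Chemokine and ERK scores stood apart in responder 1 (9.135 and 9.485). Responders 2 and 3 (7.525 and 7.352, and 8.694 and 8.592) lay between the non-responders (7.625 and 7.141, and 8.205 and 8.697). Without responder 1 chemokines (0.24, adjusted p = 0.535), ERK output (0.22, 0.135), cell cycle (-0.15, 0.0542), mesenchymal (0.11, 0.216) and angiogenic ligand genes (0.14, 0.71) no longer passed. Without non-responder 1 squamous (-0.07, 0.468), basal urothelial (0.03, 0.765), glycolysis (0.13, 0.0805), host carry-over (0.41, 0.185), ERK output (0.18, 0.0705), mesenchymal (-0.01, 0.753) and angiogenic ligand genes (0.15, 0.753) did not. Without responder 2 mesenchymal genes did not (0.12, 0.152). By limma 0 genes passed in either species, with 237 human and 242 mouse genes at an unadjusted p under 0.05. Counts were 0 and 0 by edgeR, 0 and 1 by voom and 0 and 2 by DESeq2 for human and mouse.

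The departure from additivity asks whether the combination differed from the sum of both single-drug changes. In tumour cells, squamous genes lay below that sum (median -1.19, 22 of 22 negative, adjusted p = 5.05e-06), with SPRR2D at -1.75 ± 0.81 (adjusted p = 0.662), and so did ribosomal proteins (-0.60, 25 of 25 negative, adjusted p = 9.92e-05). Both calls were lost (adjusted p = 0.875 with an estimated correlation). The squamous call held in 17 of 17 fits with 1 library left out. Without Vehicle 3, ribosomal proteins had -0.14 (adjusted p = 0.0822). ERK pathway output (-0.46, 0.00088), basal urothelial (-0.53, 0.00165), angiogenic ligand (-0.53, 0.0055), chemokine (-0.45, 0.0118), host carry-over (-0.57, 0.0451) and cholesterol synthesis genes (-0.30, 0.0469) then passed.

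Among mouse reads, interferon response genes lay below the sum (-0.47, 21 of 25 negative, adjusted p = 0.000157, and adjusted p = 0.847 with an estimated correlation), with Isg15 at -1.53 ± 0.47 (adjusted p = 0.84). So did natural killer (-1.03, 11 of 12 negative), chemokine (-0.37, 14 of 20 negative, adjusted p = 0.0418 for both) and ribosomal protein genes (-0.39, 25 of 25 negative, adjusted p = 0.00383), each with an adjusted p = 0.847 with an estimated correlation. Macrophage genes lay above it (0.32, 17 of 20 positive, adjusted p = 0.00383), with Emr1 at 0.86 ± 0.27, as did skeletal muscle (1.70, 14 of 15 positive) and FOXO genes (0.22, 16 of 20 positive, adjusted p = 0.0418 for both). These 3 calls were lost too (adjusted p = 0.847 to 0.894 with an estimated correlation), and 0 genes passed adjusted over any of the 9 lists alone. The interferon call held in 17 of 17 fits with 1 library left out. Calls were lost in 2 fits for macrophage (highest adjusted p = 0.061) and ribosomal protein genes (0.937), 8 for natural killer (0.319) and chemokine genes (0.255), 9 for FOXO targets (0.284) and 10 for skeletal muscle (0.814). Skeletal muscle had 0.07 without Combination 2 and 0.37 without Vehicle 1, and chemokines -0.08 without responder 1. Without Vehicle 3, FOXO (0.08, adjusted p = 0.284) and ribosomal protein genes (-0.02, 0.937) no longer passed, and mast cell genes did (-0.67, 0.0363). By limma 0 genes passed in either species, with 995 human and 571 mouse genes at an unadjusted p under 0.05, and 0 in either species by edgeR, voom and DESeq2.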

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

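Tests of explanations, unlike the planned departure from additivity, were chosen after the patterns were seen. Expected values for the library's ribosomal RNA level and fewer endothelial cells were written before the test. The others, with the interval of the correlation, came only after the result was seen. Intervals of medians are over genes, not tumours. In tumour cells, squamous genes rose with the combination with a median of 1.59. Reads of mouse skin are unlikely as the source, since mouse reads per human read of 16 same-named squamous genes had a median of 0.00855 (0.000862 to 0.037). Vehicle 3, rich in ribosomal RNA, did not carry the change, as the median was 1.76 (1.173 to 2.303) without it and 1.44 (1.148 to 2.2) with a covariate for ribosomal RNA. A higher share of differentiated cells and a higher level per cell could each give this pattern, and these data hold no test of it.

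Mouse endothelial genes fell after nintedanib with a median of -0.79 and with the combination with -1.04. Carry-over of human reads is unlikely, as mouse reads per human read had a median of 21.4 (5.21 to 73.9) for these genes. Dilution by growing fibroblasts or macrophages would lower pericyte genes too, and 16 pericyte and smooth muscle genes had a median change of 0.0361 (-0.361 to 0.302) after nintedanib. That interval stops short of -0.79 but does not exclude a smaller fall, so dilution is left open. An effect of nintedanib was tested in libraries not used for nintedanib against vehicle: the combination against alpelisib had a median of -0.85 (-0.9905 to -0.745), consistent with it. Fewer vessels and lower expression per vessel cell may both play a part, with no measure of vessel number here.

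Mouse cell cycle genes fell after nintedanib with a median of -0.64, while all 30 had more human than mouse reads. If the mouse reads were only carried over from human cells, both species would change alike, but after nintedanib the mouse change minus the human change had a median of -0.36 (-0.432 to -0.279), against -0.0349 (-0.0406 to -0.028) for 7582 other genes with mouse-to-human read ratios from 0.0151 to 0.415. Fewer dividing endothelial cells could lower these genes, yet within groups the cell cycle and endothelial scores had a correlation of -0.0531 (-0.587 to 0.513), and of -0.397 without the 2 libraries farthest from the middle of the endothelial scores, so that a lower endothelial share and slower division cannot be told apart. The Pearson permutation p was 0.877, and the Spearman correlation was -0.189 (p = 0.612).

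Single libraries far from the other 3 of their group were looked for in 216 groups of 4 values, and 21 were found where 10.8 would be expected by chance, about 1 in 20. The Vehicle 3 library had a mouse share of 40.63% (others 16.7 to 20.66), a ribosomal RNA share of mouse reads of 72.92% (others 2.049 to 13.09), a human ribosomal protein score of 12.32 (others 14.07 to 14.17) and a mouse ribosomal protein score of 9.921 (others 11.46 to 11.55). Vehicle 4 had a mouse share without ribosomal RNA of 20.32% (others 15.63 to 16.28), SLURP1 at 166.3 (others 22.07 to 42.41), KRTDAP at 3368 (others 1061 to 1284), CDA at 24.05 (others 5.463 to 8.024) and a mouse keratin list score of 9.611 (others 6.479 to 6.729). In Alpelisib 3, ribosomal RNA made up 44.1% of mouse reads (others 2.933 to 7.999). Alpelisib 1 had an endothelial score of 6.741 (others 7.527 to 7.623), a tip endothelial score of 7.613 (others 8.73 to 8.841), a keratin list score of 10.8 (others 7.138 to 7.183), a mouse cell cycle score of 5.754 (others 6.17 to 6.247), Clca5 at 46.69 (others 35.38 to 35.84) and Crabp1 at 1004 (others 683.6 to 736.4). Combination 2 had a human angiogenic ligand score of 9.285 (others 8.913 to 8.946), a mouse skeletal muscle score of 8.681 (others 2.493 to 2.697) and Nes at 136.8 (others 65.2 to 72.29). Combination 4 had CDA at 58.82 (others 69.15 to 70.57) and Twist2 at 147.1 (others 127.9 to 129.7).

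Departures from additivity of 9 lists were marked, all lost with an estimated correlation (adjusted p = 0.847 to 0.894). In human these were squamous genes at -1.19 (adjusted p = 5.05e-06) and ribosomal proteins at -0.60 (adjusted p = 9.92e-05). Without Vehicle 3 ribosomal proteins had -0.14 in human and -0.02 in mouse (adjusted p = 0.0822 and 0.937). In mouse these were macrophage at 0.32 and ribosomal proteins at -0.39 (adjusted p = 0.00383 for both), interferon response at -0.47 (adjusted p = 0.000157), and natural killer at -1.03, skeletal muscle at 1.70, FOXO targets at 0.22 and chemokines at -0.37 (adjusted p = 0.0418 for each). Skeletal muscle had 0.07 without Combination 2 and 0.37 without Vehicle 1, and chemokines -0.08 without responder 1.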

How the results depend on the processing

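Counts of passing genes are given first in the main fit of limma and then by setting, with higher and lower genes in brackets where given, and the cause of a difference was not tested unless said. The main fit had 52 human (46/6) and 92 mouse genes (47/45) for the combination against vehicle, 18 mouse genes (1/17) for nintedanib against vehicle, 1 mouse gene (0/1) for the combination against alpelisib, and 0 elsewhere.

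TMM scaling gave 43 human (37/6) and 85 mouse genes (41/44) for the combination and 14 mouse genes for nintedanib. With a pseudocount of 0.5 these counts were 48, 89 and 17, and with 5 they were 52, 103 and 19. By edgeR they were 40 (34/6), 69 (34/35) and 20 (0/20), with 0 mouse genes for the combination against alpelisib. By voom they were 48 (41/7), 78 (44/34) and 16, with 0 mouse genes against alpelisib and 1 (0/1) for responders. Without the expression filter they were 0, 47 (26/21) and 10, with 1 mouse gene against alpelisib (1/0, another direction than in the main fit) and 1 against nintedanib. With a minimum mean of 50 they were 34 (30/4), 60 (34/26) and 7, with 0 against alpelisib. In a fit of only the groups compared they were 7 (6/1), 26 (9/17) and 14, with 0 against alpelisib and 1 against nintedanib.

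DESeq2 gave 496 human (360/136) and 481 mouse genes (295/186) for the combination, 173 (165/8) and 113 (91/22) for alpelisib, 13 (13/0) and 93 (20/73) for nintedanib, 22 mouse genes (1/21) for the combination against alpelisib, 1 human and 30 mouse genes (17/13) against nintedanib, and 2 mouse genes (0/2) for responders. Independent filtering removed 13525 human genes for alpelisib and for nintedanib and 9186 mouse genes for alpelisib. With filtering at 0.1, added after the data were seen, alpelisib had 117 (75/42) and 88 (64/24), nintedanib 8 human (8/0) and 93 mouse, the combination 496 and 478 (292/186), and the combination against alpelisib 21 mouse genes. Without independent filtering, also added, these were 114 (73/41) and 63 (39/24), 4 (3/1) and 93, 496 and 478, and 22. Under both settings the combination against nintedanib had 1 human and 30 mouse genes, and responders 2 mouse genes.

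With a block for the replicate number, the combination had 29 human (27/2) and 46 mouse genes (23/23), nintedanib 10 mouse genes and the combination against alpelisib 0. The replicate numbers gave no sign of pairing, and 8 of 107 passing lists no longer passed in this fit.

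Further settings were chosen after the data were seen. Sample quality weights gave 1395 human (801/594) and 168 mouse genes (117/51) for alpelisib, 1204 (645/559) and 463 (269/194) for the combination, 115 mouse genes (51/64) for nintedanib and 4 for the combination against alpelisib. Without the 4 libraries rich in ribosomal RNA the combination had 0 human and 22 mouse genes (18/4), nintedanib 2, the combination against alpelisib 0 and against nintedanib 3 mouse genes. With a covariate for ribosomal RNA the combination had 261 (241/20) and 185 (128/57), nintedanib 13 and the combination against alpelisib 0. Among genes with more mouse than human reads, nintedanib had 22 (3/19), the combination 46 (17/29) and the combination against alpelisib 0.

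Leaving out each library in turn gave 0 to 97 human and 5 to 106 mouse genes for the combination, 0 to 1 human and 4 to 26 mouse genes for nintedanib, 0 to 13 mouse genes for the combination against alpelisib, 0 to 4 against nintedanib, and 0 elsewhere. Differences in mouse share ranged from -9.326 to -1.349 for alpelisib, from -4.957 to 3.02 for nintedanib and from -5.046 to 4.176 for the combination, and with ribosomal protein genes left out they were -6.76, -2.37 and -0.87.

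Of 107 list calls, 1 held with an estimated correlation (mouse, responders) and 107 with TMM scaling. With fry 7 held, all mouse (3 for nintedanib, 3 for the combination and 1 against alpelisib). Leaving out Vehicle 3, a setting added later, 10 were lost and others gained, so that 11 human lists passed for alpelisib (main fit 7) and 7 (2) for additivity, and 8 (5) and 11 (6) mouse lists for alpelisib and the combination. Without the 4 libraries 11 were lost and 1 turned in sign, mouse ribosomal proteins in the departure from additivity at 0.17 (adjusted p = 0.283). The numbers of passing lists were then 14 for human alpelisib (main fit 7), 6 (3) against alpelisib, 10 (6) against nintedanib and 8 (2) for additivity, and 9 (5) and 11 (6) for mouse alpelisib and combination. With each library of the compared groups left out in turn (added later, preset correlation), 45 of 107 calls held in every fit and 62 did not. No gene result passing in both fits turned in sign. DESeq2 made 98 of 621 stronger, quality weights 118 of 793, and leaving out single libraries made 230 of 6776 weaker and 19 stronger.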

Other observations

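Genes lower after nintedanib were looked up in libraries that share nothing with that contrast. Of the 17 mouse genes that fell after nintedanib, all 17 were also negative in the combination against alpelisib, where 48.4% of all mouse genes were negative. Their median change was -2.05 after nintedanib and -1.29 in the combination against alpelisib. Besides the genes named in the report, Pcdh12, Epha2, Exoc3l, Prc1, Kif23 and Sema3f passed. Across all genes the 2 contrasts had a correlation of 0.243 in mouse and -0.0464 in human. This comparison was chosen after the results were seen.

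Of 10324 same-named genes, 1642 had more mouse than human reads. Macrophage genes had more mouse reads in 16 of 18 cases (median ratio 63.9), fibroblast genes in 20 of 24 (11.2), pericyte genes in 12 of 16 (3.55) and natural killer genes in 7 of 11 (15.9). Mouse hypoxia genes did so in 0 of 21 cases (0.131), interferon genes in 1 of 22 (0.13), ribosomal proteins in 0 of 25 (0.177), FOXO targets in 1 of 20 (0.191) and chemokines in 9 of 20 (0.785). Lists with low ratios can hold human reads, but a median mouse share of 15.63% (without Rn45s and Lars2) also lowers ratios.

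All splits were made after the results were seen. Group names were exchanged between the libraries of 2 groups, and the count of passing genes was set beside the real one, which is included in the numbers of splits. For the combination against vehicle 1 of 35 splits, the real one, reached the real count, with 52 human genes against at most 0 and 92 mouse genes against at most 0. For nintedanib against vehicle, 2 of 100 splits reached the real 18 mouse genes, with at most 56 in another split, and in human the real count was 0 (reached by 100 of 100) with at most 30. The combination against alpelisib had 1 mouse gene, reached by 2 of 35 splits with at most 1, so that chance is not excluded, and 0 human genes (35 of 35) with at most 0. Alpelisib against vehicle had 0 genes (35 of 35) with at most 0 in both species. For the combination against nintedanib the real counts were 0 (100 of 100), with at most 825 human and 18 mouse genes in other splits. A split with 825 genes points to a structure of the samples, whose nature was not tested, and genes that vary together in few libraries can also give such a split by chance. Additivity had 0 genes (100 of 100), with at most 0 human and 2 mouse genes.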
